A study of Homo sapiens with 9 samples.

How the data were processed

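RNA from MDA-MB-231 cells, a human breast carcinoma line established from a pleural effusion, was measured on 9 one-colour Agilent arrays. Cells carried a control shRNA, EVI1 shRNA construct 1 or EVI1 shRNA construct 2, delivered by lentivirus, with 3 independent replicates in each group. The design text speaks of a matching control for each construct, but the labels give 1 control group of 3 arrays, and both constructs were compared with it.

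Per the file headers, each scanner file holds Cy3 signal intensity from Agilent Feature Extraction 10.7.3.1, which located the spots, subtracted background and corrected spatial trends on each array alone, with no normalization between arrays. Each array had 62976 spots, made from 100 ng of RNA per sample. The deposited combined table holds the same signals as raw intensity, equal within 1% for 99.7% to 99.9% of probes on each array. Its normalized columns, made by the authors, are log2 values on a scale shared by all arrays: their sorted values nearly coincide and each array reaches the same highest value of 18.7, as quantile normalization gives. The method behind those columns is not stated. They were used as an alternative only, with no further scaling.

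Spots of one probe were averaged, the processed signal was taken as log2, and the array's 75th percentile over all 50599 non-control probes was subtracted. Printed log2 signals have the mean of the 9 percentiles added back. A probe was kept if it was well above background on at least 2 of 3 arrays in at least 1 group, which left 30652 probes. Symbols came from matching the files' transcript accessions (28174 probes), current symbols (2618) or older symbols (620) to the gene table at hand, while 19187 probes kept the name in the files. The probe with the highest mean over the 9 arrays stood for each gene, which gave 22907 genes and unnamed transcripts. Coordinates are those in the files, on hg19/GRCh37. No exon annotation was at hand and the labels do not give the hairpin sequences, so neither the part of a transcript under a probe nor the hairpin target is stated.

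Signal over background sets the limit of detection on arrays. Between 52% and 60.1% of probes were well above background per array and 0 probes were saturated. With 3 arrays per group the number of arrays limits the precision: the median standard error of a construct's log2 fold change was 0.187, and the smallest change past the threshold was 0.388 on the log2 scale for construct 1 and 0.31 for construct 2. A gene above background on no array of one of the groups compared is given as an at-least fold, computed with the dimmer side raised to the lowest well-above-background signal of each array. For a gene above background on 1 array of a group no size is given.

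All 9 arrays entered one limma fit with a mean per group and an empirical Bayes spread. Contrasts were tested 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The contrasts were each construct against control, the mean of both constructs against control, and construct 2 against construct 1. Printed errors of fold changes are standard errors of that fit. Errors of group signals are standard deviations over 3 arrays. MECOM probes were tested one by one, with an exact permutation test beside the fit.

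28 gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists. They were genes of mitosis, DNA replication, p53 targets, pro-apoptotic and anti-apoptotic genes, G protein-coupled receptor (GPCR) ligands, GPCRs, G proteins and RGS genes, TGF-beta targets, mesenchymal and epithelial genes, extracellular proteases and their inhibitors, integrins and adhesion, NF-kappaB inflammatory genes, interferon response, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, ATF4 and the unfolded protein response, immediate early genes, ribosome biogenesis and MYC targets, oxidative phosphorylation, breast stem and progenitor genes, reported EVI1 targets, and luminal breast, leukocyte, endothelial and fibroblast markers. Of 977 list entries, 886 were measured. Camera ranks a list against the other genes, while fry, an alternative, asks whether a list's genes move one way on balance. None of the calls made by camera over all arrays held when the correlation was estimated for each list, and that adjusted p is given with each of them.

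Named genes were chosen by rule: the 8 largest rises and 8 largest falls per comparison with control (5 between the constructs) among genes past the threshold, above background on both sides and with no overlap between the arrays of the groups compared. Up to 3 genes per direction given as bounds were added, with up to 4 members with the smallest adjusted p of each list that was called or had at least 3 members past the threshold. MECOM and KISS1 were always named. Comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, unless stated otherwise.

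Alternatives were quantile normalization, a percentile over probes above background on all 9 arrays, normexp background correction with an offset of 50, the authors' normalized values, no filter and a stricter filter, every probe or the mean of a gene's probes, only the groups compared in the fit, an intensity trend with a robust spread, array weights, slide as a block, the replicate number as a block, and leaving out each array. Slide membership came from the scanner files. The pipeline was tested on simulated data. With an equal spread in all groups, 39.8% of simulated 2-fold and 80.4% of 4-fold changes with construct 1 passed the threshold, and 6 of 22678 unchanged genes were called. With the spread each group showed and 98 genes changed 2-fold and 98 changed 4-fold per construct, 85 of 22677 unchanged genes were called for construct 1, against 9 when only the groups compared entered the fit. For construct 2 those counts were 37 and 39. The number called in error depends on how many genes change, so these counts do not carry over as a share of the real calls. A simulated shift of the mitosis list was called, with 0 of the 27 other lists. The genes were simulated as independent, while the estimated correlation in the real data was 0.752 for the mitosis list and 0.393 for the NF-kappaB list. The simulation therefore does not check for false calls of lists whose genes move together.

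Tools were R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8), jsonlite 2.0.0, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.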

Results

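The series measured gene expression in MDA-MB-231 breast cancer cells after short hairpin RNAs (shRNAs) against EVI1 had been introduced. EVI1 is a zinc finger transcription factor encoded by the MECOM locus on chromosome 3. There were 3 control arrays, 3 arrays of construct 1 and 3 of construct 2, each replicate from a separate experiment. Between 52% and 60.1% of the 50599 probes were well above background on each array, and the 75th percentile of signal ran from 461 to 702. The arrays sat on 4 slides: control replicates 1 and 2 shared slide 1 with construct 1 replicates 2 and 3, control replicate 3 and construct 1 replicate 1 were each alone on a slide, and all 3 construct 2 arrays shared slide 4. Slide and construct 2 therefore cannot be told apart, while construct 1 can be compared with control inside slide 1. Across genes, arrays of one group correlated at r 0.982 to 0.992, control and construct 1 arrays at 0.972 to 0.986, and control and construct 2 arrays at 0.961 to 0.968. The median standard deviation of a gene over 3 arrays was 0.242 (log2) in controls, 0.246 with construct 1 and 0.0861 with construct 2. The construct 2 value holds no difference between slides, unlike the others. Pairs sharing a slide correlated at 0.991 for controls, 0.992 for construct 1 and 0.991 to 0.992 for construct 2. Pairs of a group on different slides gave 0.982 to 0.987 for controls and 0.983 for construct 1. With slide as a block the correlation within a slide was estimated at 0.574. The main fit treated all arrays as independent and pooled these spreads.

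MECOM, the targeted gene, fell with both constructs. Its brightest probe (A_33_P3888629, chromosome 3, 168801356 to 168801415) read 11.14 ± 0.25 (log2 signal, SD, n = 3) in controls, 10.01 ± 0.26 with construct 1 and 9.32 ± 0.07 with construct 2. The construct 1 level was 45.8% of control (log2 fold change -1.12 ± 0.17, limma adjusted p = 0.00804 over probes) and the construct 2 level 28.4% (-1.82 ± 0.17, adjusted p = 0.000366). Over both constructs the level was 36.1% of control (-1.47 ± 0.15, adjusted p = 0.0015). A second probe (A_23_P317324, 168806839 to 168806898) gave 41.4% and 21.6% of control (-1.27 ± 0.25, adjusted p = 0.0194, and -2.21 ± 0.25, adjusted p = 0.000704), with the construct 1 call lost in 4 of 22 alternative settings (highest adjusted p = 0.0764). Another probe, at higher coordinates of the locus (A_24_P320103, 169099038 to 169099097), is annotated to a different transcript and need not measure the same forms. It was dim, at 5.20 ± 0.18 in controls, 4.73 ± 0.15 with construct 1 and 5.51 ± 1.43 with construct 2. It did not pass for either construct, although 5 of the 6 construct arrays lay below every control. On the brighter probes every construct array lay below every control array, for which the 2-sided exact permutation test gives p = 0.1 with 3 arrays against 3 and p = 0.0119 with 6 against 3, the smallest values these designs allow. MECOM was lower with construct 2 than with construct 1 (-0.69 ± 0.17, adjusted p = 0.0163), a call that was lost with slide as a block (adjusted p = 0.0647) and without construct 2 replicate 1 or replicate 3 (adjusted p = 0.0539 and 0.0584). Inside slide 1, with 2 arrays on each side, the fall with construct 1 was -1.11 ± 0.19 (limma adjusted p = 0.0373). With the construct 2 arrays out of the fit, the adjusted p for construct 1 was 0.0495 over probes.

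KISS1, which encodes the ligand of a G protein-coupled receptor and is known as a metastasis suppressor, was measured by one probe (chromosome 1, 204161970 to 204162029). It fell with construct 2 (-1.84 ± 0.36, limma adjusted p = 0.006) and over both constructs (-1.59 ± 0.31, adjusted p = 0.0121). With construct 1 its log2 fold change was -1.34 ± 0.36 and did not pass (adjusted p = 0.053), and the constructs did not differ by the test (-0.50 ± 0.36, adjusted p = 0.305). Inside slide 1 the construct 1 value was -0.71 ± 0.25 (adjusted p = 0.197). The call for construct 2 was lost with slide as a block, and that over both constructs with array weights and without control replicate 2.

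**Figure D1:**
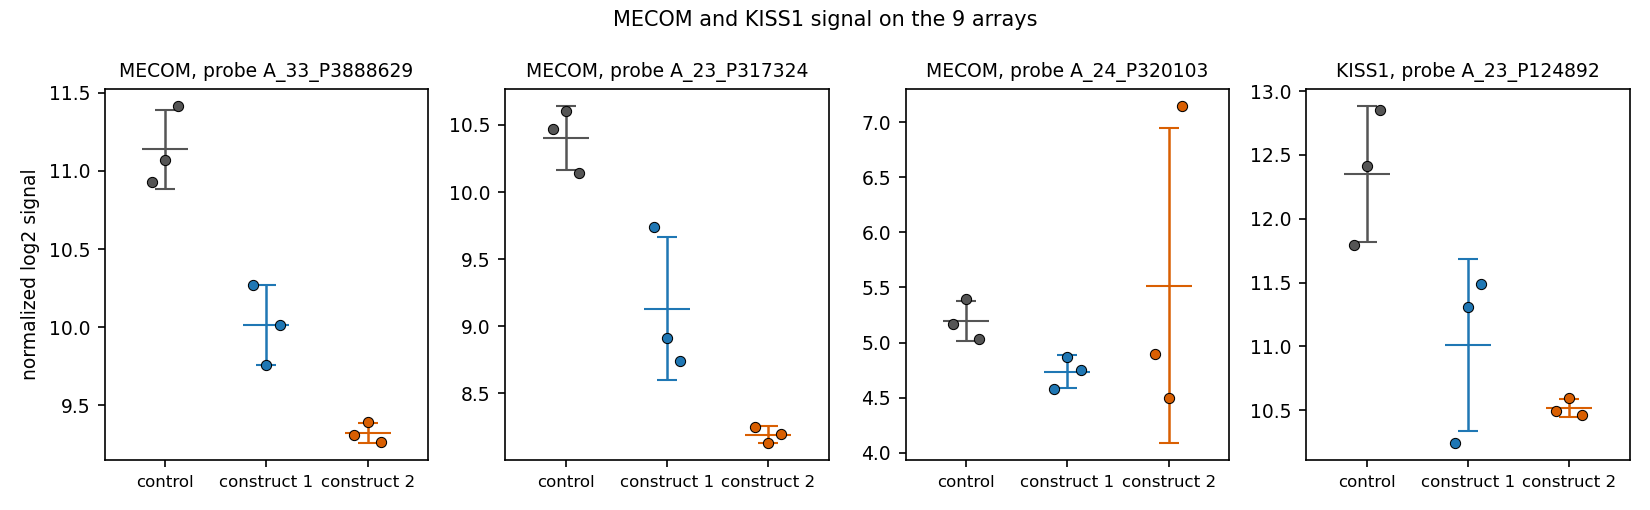
Normalized log2 signal of 3 MECOM probes and the KISS1 probe, with one point per array, a horizontal bar for the group mean and whiskers for 1 SD (n = 3). On the 2 brighter MECOM probes all 6 construct arrays lie below the 3 controls, while on the dim probe A_24_P320103 5 construct arrays do and 1 construct 2 array lies above them, at 7.15.

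Construct 1 against control asks what the first hairpin changed. SCARNA11, a small Cajal body RNA, rose most (19.2-fold, log2 fold change 4.27 ± 0.15, limma adjusted p = 2.2e-05). EPHB6, an ephrin receptor gene whose product lacks kinase activity, rose 13-fold (3.70 ± 0.22), and CST7, which encodes a cysteine protease inhibitor, 11.7-fold (3.55 ± 0.30). KLRC1, a natural killer cell receptor gene (11.1-fold, 3.48 ± 0.23, adjusted p = 0.000313), and CRTAM, a T cell surface molecule gene (3.43 ± 0.29), rose with them. IFITM10 (3.35 ± 0.26), NGFR, a neurotrophin receptor (3.29 ± 0.28), and CREB3L3 (3.24 ± 0.31) also rose. The largest falls were of SAA2, an acute-phase protein gene (6.09-fold lower, -2.61 ± 0.37, adjusted p = 0.00613), ACTG2, a smooth muscle actin gene (-2.50 ± 0.28), CCND2, a D-type cyclin gene (5.54-fold lower, -2.47 ± 0.30), GPC6 (-2.43 ± 0.29), CHI3L2 (5.39-fold lower, -2.43 ± 0.16) and HLA-DOA (-2.40 ± 0.22), whose other kept probe lay the opposite way at 0.52. TIE1 (-2.40 ± 0.48) and ARC (-2.37 ± 0.58) fell too, but lost their calls in 7 and 11 of 23 alternative settings.

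Some genes were above background on one side only. FAP, a fibroblast surface protease gene, was at least 4.39-fold higher with construct 1, SPP1 (osteopontin) at least 3.78-fold and NOL4L at least 3.53-fold. KCTD4 was at least 4.37-fold lower, MARCHF1 at least 3.73-fold and AFP at least 2.37-fold, the last with its call lost in 12 of 23 settings.

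Extracellular proteases and their inhibitors rose with construct 1: 11 of 38 measured members were higher and 0 lower over all genes, and 18 higher and 1 lower adjusted over the list alone. The list median was 0.43 (camera, adjusted p = 2.18e-05, and adjusted p = 0.106 with an estimated correlation). MMP3, stromelysin 1, rose 8.62-fold (3.11 ± 0.34), CTSD, cathepsin D, 3.64-fold (1.87 ± 0.16), TIMP1, a metalloproteinase inhibitor, 3.21-fold (1.68 ± 0.18) and MMP15 3.17-fold (1.67 ± 0.13). Interferon response genes rose as well, with 12 of 47 higher and 0 lower, 16 higher and 1 lower adjusted over the list alone, and a median of 0.30 (adjusted p = 2.64e-05, and adjusted p = 0.674 with an estimated correlation). Among them were the antiviral genes RSAD2 (1.84 ± 0.23), EPSTI1 (1.14 ± 0.17), ISG20 (1.05 ± 0.16) and SAMD9 (0.81 ± 0.12). Of the ATF4 and unfolded protein response genes, 8 of 33 were higher and 0 lower (8 and 1 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.00321, and adjusted p = 0.674 with an estimated correlation). HERPUD1, which acts in disposal of misfolded endoplasmic reticulum proteins (1.16 ± 0.16), the chaperone gene HSPA5 (0.83 ± 0.14) and the transcription factor gene XBP1 (0.79 ± 0.12) were higher. With construct 2 the ATF4 list had a like median of 0.30 and was not called (camera adjusted p = 0.283). There 10 of 33 genes were higher and 3 lower (12 and 3 adjusted over the list alone).

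Epithelial genes moved both ways with construct 1: 6 of 37 were higher and 2 lower (7 and 3 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.0294, and adjusted p = 0.674 with an estimated correlation). The tight junction gene CLDN4 (1.48 ± 0.19) rose, while the desmosome gene DSP (-1.47 ± 0.16) and the receptor gene ERBB3 (-1.61 ± 0.16) fell. With construct 2 the epithelial median was 0.24, with 9 of 37 higher and 4 lower (9 and 5 adjusted over the list alone). The list was not called there (camera adjusted p = 0.377). Of 14 fibroblast markers, 8 were measured. With construct 1, 4 were higher and 0 lower (5 and 0 adjusted over the list alone). Their median was 1.53 (camera adjusted p = 5.98e-05, and adjusted p = 0.106 with an estimated correlation). COL1A1, a chain of type I collagen (1.94 ± 0.29), PDGFRB (1.70 ± 0.23) and LUM (2.20 ± 0.46) rose with FAP, and LUM lost its call in 7 of 23 settings. The list median was 0.26 with no filter on dim probes, 0.39 with the stricter filter and 0.76 with normexp, and the list was still called with each. The other 6 markers, COL3A1, DCN, PDGFRA, THY1, POSTN and PDPN, were above background on no array. COL1A1, PDGFRB and FAP also belong to the mesenchymal list, in which 4 of 25 genes were higher and 2 lower (8 and 2 adjusted over the list alone) and which was not called (median 0.16, adjusted p = 0.472).

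Cell cycle lists lay lower with construct 1, although few single genes passed. Neither list passed with fry (adjusted p = 0.147 for mitosis and 0.0966 for DNA replication). The mitosis list had a median of -0.43, with 1 of 35 genes lower and 0 higher (0 and 0 adjusted over the list alone, adjusted p = 1.95e-07, and adjusted p = 0.674 with an estimated correlation). The DNA replication list had a median of -0.32, with 4 of 40 lower and 0 higher (8 and 0 adjusted over the list alone, adjusted p = 2.1e-07, and adjusted p = 0.674 with an estimated correlation). AURKB, a mitotic kinase gene (-0.71 ± 0.16), MCM3 (-0.60 ± 0.15), GINS1 (-0.56 ± 0.14) and POLD1 (-0.49 ± 0.13) fell, and each lost its call when only the groups compared entered the fit. Ribosome biogenesis and MYC target genes had a median of -0.20, with 1 of 36 lower, the nucleolar methyltransferase gene FBL (-0.67 ± 0.16), and 0 higher (0 and 0 adjusted over the list alone, adjusted p = 0.0111, and adjusted p = 0.804 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.21, with 5 of 34 higher and 5 lower (5 and 8 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.674 with an estimated correlation). The glycolytic gene PGK1 (-1.04 ± 0.14) and the collagen cross-linking enzyme gene LOX (-0.93 ± 0.15) fell, and NDRG1 (0.86 ± 0.15) rose. The hypoxia, epithelial and ribosome lists lost their calls in 10, 7 and 6 of 26 alternative settings.

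In all, 2009 of 22907 genes changed with construct 1 (8.77%), 1046 higher and 963 lower, of which 761 changed at least 2-fold, and 5609 had an unadjusted p under 0.05. Inside slide 1, 726 genes passed, and 515 of the 2009 calls were called there as well. The mitosis, DNA replication, protease, interferon, ATF4, epithelial and fibroblast lists were also called inside slide 1, with medians of -0.36, -0.32, 0.52, 0.26, 0.37, 0.29 and 1.29, while the hypoxia and ribosome lists were not (adjusted p = 0.202 for both). Breast stem and progenitor genes (median 0.24, adjusted p = 0.0314), reported EVI1 targets (0.24, adjusted p = 0.0405) and immediate early genes (0.11, adjusted p = 0.0405) were called upward inside slide 1 and not over all arrays. Of these 10 calls inside slide 1, 0 held with the correlation estimated for each list (the lowest was adjusted p = 0.735 with an estimated correlation). With only the groups compared in the fit, 423 genes passed instead of 2009. In simulated data with the spread of each group and few changed genes, 85 of 22677 unchanged genes were called for construct 1, and 9 with only the groups compared. They made up 37.3% and 8.91% of all calls in those simulated fits. Without control replicate 2 the count was 755, without control replicate 3 1190, without construct 1 replicate 2 1092, and without construct 2 replicate 1, 2 or 3 1226, 1288 and 1226.

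Construct 2 against control asks the same of the second hairpin, and 5 genes of the inflammatory list were among its 8 largest rises. LCN2, which encodes the iron-sequestering protein lipocalin 2, rose 93.8-fold (log2 fold change 6.55 ± 0.62, limma adjusted p = 0.000364). The neutrophil chemokine genes CXCL1 (41.0-fold, 5.36 ± 0.42) and CXCL8 (20.1-fold, 4.33 ± 0.43), the growth factor gene CSF3 (31.5-fold, 4.98 ± 0.40) and the cytokine genes IL24 (20.8-fold, 4.38 ± 0.22) and IL1A (20.2-fold, 4.34 ± 0.32) rose with it. ASB2 (58.2-fold, 5.86 ± 0.66) and PDZK1IP1 (51.7-fold, 5.69 ± 0.39) completed the largest rises. The largest falls were of ATP10A, a phospholipid flippase gene (18.9-fold lower, -4.24 ± 0.47, adjusted p = 0.000633), the immediate early gene EGR1 (15.4-fold lower, -3.95 ± 0.46), the phosphodiesterase gene PDE1C (14.8-fold lower, -3.88 ± 0.52), the cancer-testis genes SPANXA1 (-3.77 ± 0.53) and SPANXB1 (-3.48 ± 0.38), COX7B2 (-3.87 ± 0.65), SLAMF7 (-3.67 ± 0.64) and FRMD3 (-3.39 ± 0.66). PLA2G2F was at least 15.1-fold higher, OR51B6 at least 10.46-fold and CCKBR, the gastrin receptor gene, at least 8.13-fold. ARC was at least 14.3-fold lower, TCF4 at least 10.04-fold and ID4 at least 7.65-fold. COX7B2, SLAMF7, FRMD3 and ID4 lost their calls with slide as a block.

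NF-kappaB inflammatory genes rose together with construct 2: 28 of 35 were higher and 0 lower (28 and 1 adjusted over the list alone), with a median of 1.58 (camera, adjusted p = 8.04e-13, and adjusted p = 0.546 with an estimated correlation). IL1B rose 7.94-fold (2.99 ± 0.16), C3, the central complement protein gene, 17.7-fold (4.14 ± 0.25) and CXCL3 10.49-fold (3.39 ± 0.21). On the 3 construct 2 arrays the list median lay 1.57, 1.57 and 1.58 above the control mean, against -0.32 to 0.46 on the control arrays. The chemokines also belong to the GPCR ligands, of which 13 of 31 were higher and 6 lower (14 and 6 adjusted over the list alone), with no call for the list (median 0.38, adjusted p = 0.15). Of the pro-apoptotic genes, 13 of 31 were higher and 5 lower (15 and 5 adjusted over the list alone, median 0.36, adjusted p = 0.15, not called). The BH3-only genes BIK (11.04-fold, 3.46 ± 0.30), BMF (5.49-fold, 2.46 ± 0.23) and BID (1.14 ± 0.12) and the TRAIL receptor gene TNFRSF10B (1.01 ± 0.12) rose.

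Oxidative phosphorylation genes rose with construct 2, 10 of 39 higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.000923, and adjusted p = 0.739 with an estimated correlation). Examples were COX4I1 (0.78 ± 0.12), SDHB (0.74 ± 0.14), NDUFB9 (0.68 ± 0.11) and ATP5F1B (0.66 ± 0.13). The mitosis list had a median of -0.37, with 9 of 35 lower and 0 higher (9 and 0 adjusted over the list alone, adjusted p = 6.22e-05, and adjusted p = 0.739 with an estimated correlation). BIRC5 (-0.94 ± 0.16), the topoisomerase gene TOP2A (-0.90 ± 0.22) and KIF20A (-0.85 ± 0.14) fell. The DNA replication list had a median of -0.29, with 14 of 40 lower and 1 higher (17 and 1 adjusted over the list alone, adjusted p = 6.22e-05, and adjusted p = 0.739 with an estimated correlation). GINS4, part of the replicative helicase (-1.89 ± 0.18), E2F8 (-1.56 ± 0.19) and the primase gene PRIM1 (-1.03 ± 0.11) fell. Breast stem and progenitor genes had a median of -0.32, with 12 of 29 lower and 3 higher (12 and 5 adjusted over the list alone, adjusted p = 0.0389, and adjusted p = 0.555 with an estimated correlation). SOX2, a pluripotency factor gene, was at least 2.96-fold lower, and TSPAN8 (-2.43 ± 0.38), the NOTCH ligand gene JAG1 (-1.64 ± 0.24) and BMI1 (-1.55 ± 0.17) fell. That list lost its call in 11 of 26 settings.

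In all, 7473 of 22907 genes changed with construct 2 (32.6%), 4343 higher and 3130 lower (58.1% higher, and 50.7% with quantile normalization), of which 2896 changed at least 2-fold, and 10237 had an unadjusted p under 0.05. All construct 2 arrays came from one slide, so no value inside a slide can be given. With slide as a random block 1462 genes passed. For construct 1, 2126 passed with slide as fixed terms, an unlike model, so these counts cannot be set against each other. Without construct 2 replicate 1, 2 or 3 the construct 2 count was 4546, 4851 and 4525.

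Construct 2 against construct 1 tests the difference between the hairpins, and genes of the inflammatory list were among the largest. LCN2 was 475-fold higher with construct 2 (log2 difference 8.89 ± 0.62, limma adjusted p = 7.83e-05), PDZK1IP1 168-fold (7.39 ± 0.39), CXCL1 81.0-fold (6.34 ± 0.42), C3 54.8-fold (5.78 ± 0.25) and ASB2 37.1-fold (5.21 ± 0.66). Lower with construct 2 were INHBB, the inhibin beta B gene (24.9-fold lower, -4.64 ± 0.34), the integrin gene ITGA10 (19.96-fold lower, -4.32 ± 0.24), the trefoil factor gene TFF2 (19.3-fold lower, -4.27 ± 0.15), ATP10A (-4.22 ± 0.47) and ANO2 (-4.24 ± 0.87), the last with its call lost with slide as a block. PLA2G2F was at least 17.0-fold higher with construct 2, PDGFB at least 12.3-fold and CCKBR at least 9.13-fold. EPHB6 was at least 17.9-fold lower, ID4 at least 14.1-fold and SPOCK3 at least 9.85-fold.

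Of the NF-kappaB inflammatory genes, 26 of 35 were higher with construct 2 than with construct 1 and 0 lower (28 and 1 adjusted over the list alone, median 1.53, camera adjusted p = 7.62e-13, and adjusted p = 0.332 with an estimated correlation). Interferon response genes went the other way, with 19 of 47 lower and 3 higher (22 and 5 adjusted over the list alone, median -0.39, adjusted p = 6.56e-05, and adjusted p = 0.626 with an estimated correlation). RSAD2 (-2.71 ± 0.23), the interferon regulator gene IRF7 (-2.56 ± 0.16), SAMD9L (-1.64 ± 0.16) and SAMD9 (-1.24 ± 0.12) were lower. Fibroblast markers were lower too, 5 of 8 lower and 0 higher (5 and 0 adjusted over the list alone, median -1.78, adjusted p = 0.00887, and adjusted p = 0.332 with an estimated correlation). PDGFRB (-1.95 ± 0.23) and COL1A1 (-1.89 ± 0.29) were lower, and FAP at least 2.95-fold lower. LUM was lower too, but no size is given because it was above background on only 1 construct 2 array. The call was lost with no filter on dim probes (median 0.08, adjusted p = 0.058) and with the stricter filter (-0.35, adjusted p = 0.177).

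Breast stem and progenitor genes were lower with construct 2 than with construct 1, 13 of 29 lower and 3 higher (15 and 5 adjusted over the list alone, median -0.64, adjusted p = 0.00887, and adjusted p = 0.332 with an estimated correlation). The transporter gene ABCG2 (-1.60 ± 0.20) and BMI1 (-1.23 ± 0.17) were among them. The list of reported EVI1 targets, which mixes genes described as raised and as lowered by EVI1, had 14 of 31 lower and 4 higher (15 and 4 adjusted over the list alone, median -0.44, adjusted p = 0.00887, and adjusted p = 0.332 with an estimated correlation). CCND2 was 18.8-fold higher (4.23 ± 0.30), and the receptor gene KDR (-2.24 ± 0.27), the integrin gene ITGB4 (-1.82 ± 0.20) and the gluconeogenesis gene FBP1 (-1.33 ± 0.15) were lower. Ribosome biogenesis and MYC target genes were higher, 14 of 36 higher and 1 lower (14 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.0113, and adjusted p = 0.799 with an estimated correlation), with FBL at 1.03 ± 0.16. Oxidative phosphorylation genes were higher, 12 of 39 higher and 0 lower (12 and 0 adjusted over the list alone, median 0.25, adjusted p = 0.00729, and adjusted p = 0.736 with an estimated correlation), with NDUFC1 at 1.18 ± 0.14. In all, 7847 genes differed between the constructs (34.3%), 4514 higher and 3333 lower with construct 2 (57.5% higher, and 50.7% with quantile normalization), 3078 of them at least 2-fold, and 10517 had an unadjusted p under 0.05. With slide as a random block 2147 genes differed, and without construct 2 replicate 1, 2 or 3 the count was 4967, 5207 and 5035.

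**Figure D2:**
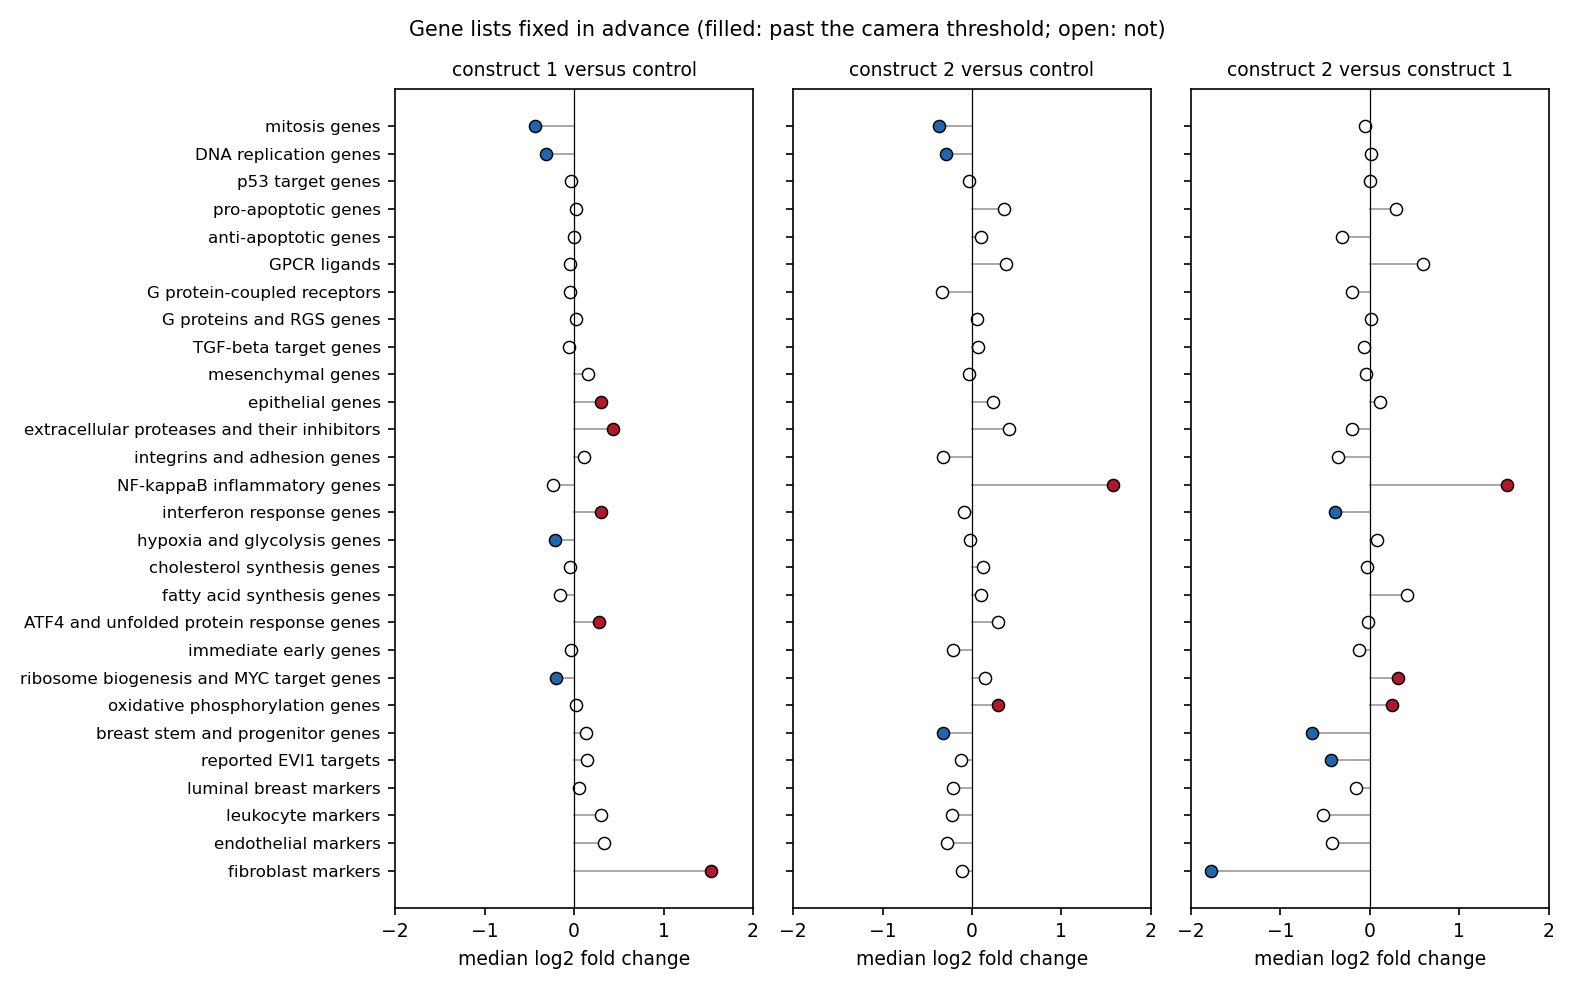
Median log2 fold change of the measured members of each of the 28 gene lists in 3 comparisons, where filled points passed the camera threshold (red upward, blue downward) and open points did not. The NF-kappaB list lies at 1.58 with construct 2 and at -0.23, not called, with construct 1, and the fibroblast list lies at 1.53 with construct 1 and at -0.11, not called, with construct 2.

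Both constructs together against control ask what changed on the average of the hairpins, which can be carried by either. MMP3 rose 5.97-fold on average (log2 fold change 2.58 ± 0.29, limma adjusted p = 0.00193) and SCARNA11 5.67-fold (2.50 ± 0.13). MMP3 was higher with each construct (3.11 ± 0.34 and 2.05 ± 0.34 for construct 1 and 2), while the mean for SCARNA11 came mostly from construct 1 (4.27 ± 0.15 and 0.74 ± 0.15). KLRC1 rose 5.49-fold (2.46 ± 0.20, from 3.48 and 1.44 by construct), KLRC4, its neighbour on chromosome 12, 4.91-fold (2.30 ± 0.23), CST7 5.37-fold (2.42 ± 0.26, from 3.55 and 1.30) and the pro-apoptotic gene BMF 4.81-fold (2.27 ± 0.20, from 2.08 and 2.46). The epoxide hydrolase gene EPHX2 (2.50 ± 0.51) and the natriuretic peptide gene NPPB (2.46 ± 0.57) rose too, and both lost their calls with array weights and without control replicate 2. PDE1C fell 6.52-fold (-2.70 ± 0.45), ADTRP 5.34-fold (-2.42 ± 0.20) and EPB41L4A 5.33-fold (-2.41 ± 0.37). Further falls were of the protease-activated receptor gene F2RL2 (-2.28 ± 0.45), the epoxygenase gene CYP2J2 (-2.09 ± 0.24), the chemokine receptor gene CCR1 (-2.07 ± 0.38), RIMS1 (-2.06 ± 0.26) and CHI3L2 (-2.02 ± 0.14). With construct 1 alone NPPB, PDE1C and F2RL2 did not pass (adjusted p = 0.0758, 0.108 and 0.0953). NOL4L was at least 3.28-fold higher and INSYN2A at least 2.11-fold, and MARCHF1 was at least 2.89-fold lower, ESM1 at least 1.72-fold and ZBED2 at least 1.60-fold.

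By list, proteases and their inhibitors rose on the average of the constructs, with 15 of 38 higher and 1 lower (18 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.000527, and adjusted p = 0.271 with an estimated correlation). With construct 2 alone this list was not called (median 0.41, 14 of 38 higher and 3 lower, 15 and 3 adjusted over the list alone, adjusted p = 0.114). MMP15 (1.95 ± 0.11), CTSD (1.25 ± 0.14) and the urokinase receptor gene PLAUR (0.86 ± 0.11) rose with MMP3. The mitosis list had 7 of 35 lower and 0 higher (8 and 0 adjusted over the list alone, median -0.36, adjusted p = 1.51e-08, and adjusted p = 0.618 with an estimated correlation), and the DNA replication list 12 of 40 lower and 1 higher (16 and 1 adjusted over the list alone, median -0.34, adjusted p = 2.48e-08, and adjusted p = 0.618 with an estimated correlation). GINS4 (-1.23 ± 0.16) and KIF20A (-0.64 ± 0.12) fell. Like the proteases, the other lists called on the average had been called with one construct and not the other: NF-kappaB genes (median 0.96, 22 of 35 higher and 0 lower, 24 and 0 adjusted over the list alone, adjusted p = 1.51e-08, and adjusted p = 0.618 with an estimated correlation), oxidative phosphorylation (median 0.16, 6 of 39 higher and 0 lower, 6 and 0 adjusted over the list alone, adjusted p = 0.0198, and adjusted p = 0.886 with an estimated correlation) and fibroblast markers (median 0.63, 4 of 8 higher and 0 lower, 4 and 0 adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.618 with an estimated correlation). The fibroblast call was lost in 4 of 26 settings, among them without control replicate 3 (adjusted p = 0.102).

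On the average of the constructs 3960 genes changed (17.3%), 2176 higher and 1784 lower (54.95% higher, and 48.4% with quantile normalization), 1051 of them at least 2-fold, and 7654 had an unadjusted p under 0.05. Without control replicate 2 the count was 1421, and without construct 2 replicate 1, 2 or 3 it was 2328, 2443 and 2300. With array weights it was 684, with slide as a random block 1865 and with no filter on dim probes 2048. Taken construct by construct, 768 genes were called in the same direction with both, 411 higher and 357 lower, which is 38.2% of the construct 1 calls. Independent lists of those sizes, which leave the shared controls out of account, would share 330 (198 higher and 132 lower). Unchanged groups simulated against the same controls shared 1.33 on average and 7 at most. With no gene changed hardly any gene is called, so that count had to be small. It cannot say how far changes of these sizes would overlap without a shared effect. The shared count was 252 without control replicate 2, 1304 without control replicate 1, 454 without control replicate 3, 462 without construct 1 replicate 2, and 366, 391 and 368 without construct 2 replicate 1, 2 and 3. In opposite directions 231 genes were called, where independent lists would give 326. The fold changes of the constructs correlated across genes at r = 0.263 (Spearman 0.272), below the 0.582 (0.573) that the shared control arrays alone gave in simulations, although their covariance was larger (0.111 against 0.0617). That r was 0.142 without construct 1 replicate 1, 0.364 without control replicate 1, 0.163 with slide as a block and 0.095 without the arrays alone on their slide. Genes are not independent replicates, and the 3 controls were too few to be divided between the constructs. With only the groups compared in each fit, 188 genes were shared and 39 were opposite.

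**Figure D3:**
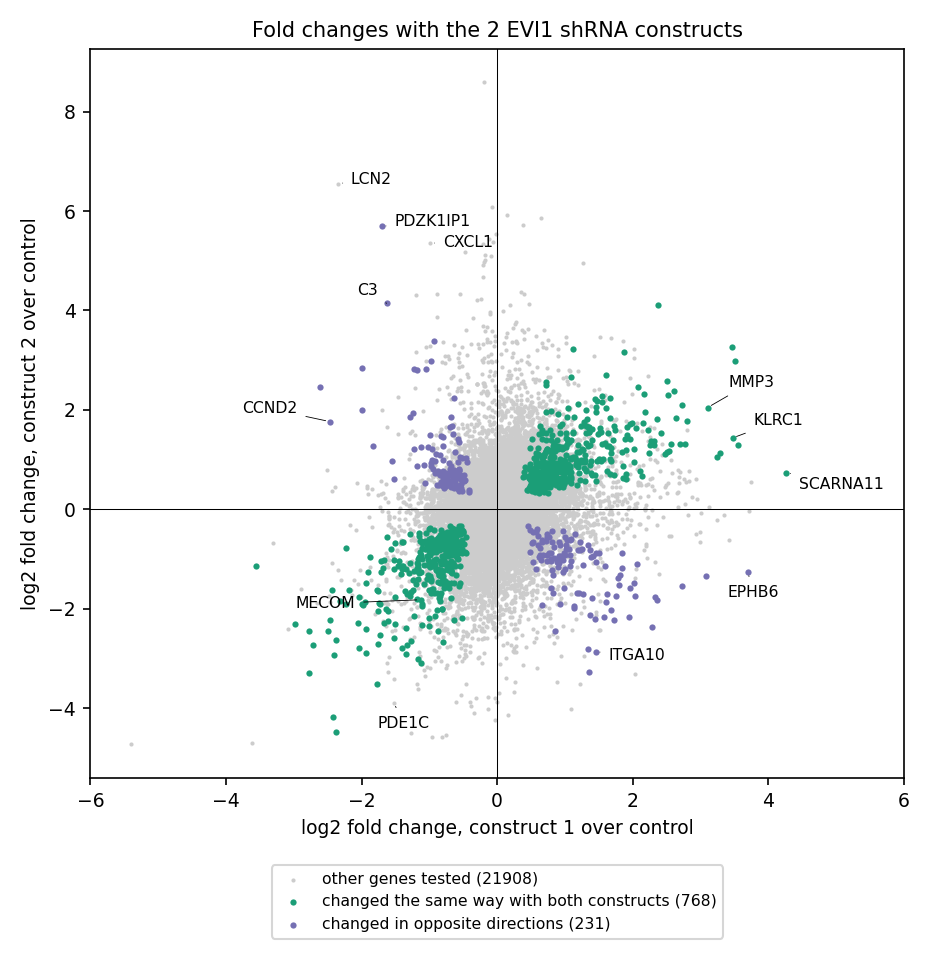
Log2 fold change of each of the 22907 genes with construct 1 (horizontal) and construct 2 (vertical) over control, with genes called with both constructs in colour. The 768 genes that changed the same way lie at the upper right and lower left, and the 231 that changed in opposite directions at the upper left and lower right.

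**Figure D4:**
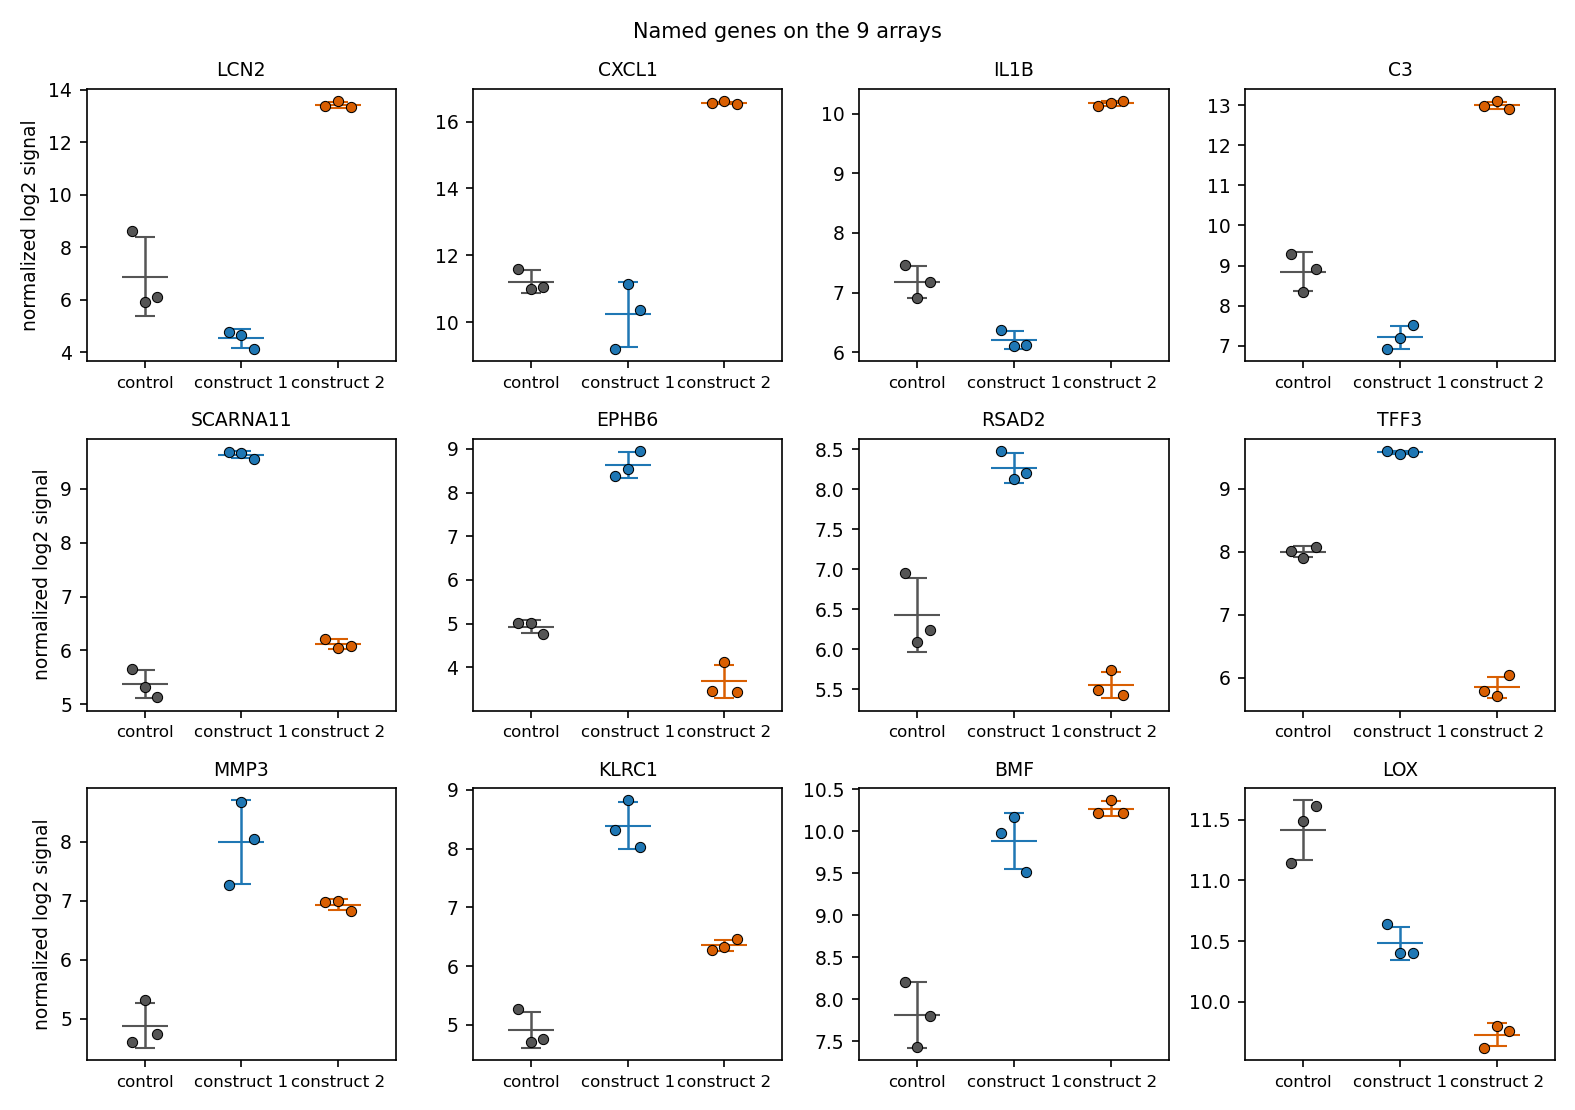
Normalized log2 signal of 12 named genes on the 9 arrays, with one point per array, a bar for the group mean and whiskers for 1 SD (n = 3). LCN2, CXCL1, IL1B and C3 are higher on the construct 2 arrays, SCARNA11, EPHB6, RSAD2 and TFF3 on the construct 1 arrays, MMP3, KLRC1 and BMF with both constructs, and LOX is lower with both.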

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

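The counts over other splits, the scaling alternatives and slide as a block were planned, while their use to weigh an explanation and the remaining tests in this part were chosen after the results were seen. Each result here stands out because the constructs' effects against the same controls differed by a test of the difference itself. In all, 7847 genes differed between the constructs, and 231 genes were called in opposite directions. Of these, 113 were higher with construct 1 and lower with construct 2 and 118 the reverse. Each of them also differed between the constructs, which adds nothing, since the difference of opposite changes is larger than either change. Independent lists of those sizes would give 326 opposite calls, and 39 were opposite with only the groups compared in each fit.

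Inflammatory genes were higher with construct 2 than with construct 1, by a median of 1.533 (log2). Scaling between arrays is argued against, since the lowest median against control over 4 scaling alternatives was 1.328. Between the constructs the lowest median over all 26 alternative settings, the scalings included, was 1.216. A response in proportion to the fall of MECOM is argued against as the only cause. The fall with construct 1 was 0.619 of that with construct 2, which would put the construct 1 median at 0.976, and it was -0.234. A proportional response with a slide effect on the construct 2 arrays added is not excluded. Slide or scan and construct 2 cannot be told apart, because no other group was on slide 4, although the slide means inside the control and construct 1 groups differed by at most 0.207, with single control arrays from -0.32 to 0.46. An effect of this hairpin on genes other than MECOM, a stronger response to less EVI1 and a slide effect may each account for the rise, and only the proportional form of the response was tested.

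Fibroblast markers were lower with construct 2 than with construct 1, by a median of -1.777, because COL1A1, PDGFRB, LUM and FAP were higher with construct 1 than in controls. Fibroblasts in the construct 1 cultures are argued against, since 6 of the 14 markers, with the abundant fibroblast transcripts COL3A1 and DCN among them, were well above background on no array. Slide as the whole cause is argued against by the median of 1.292 inside slide 1, which holds 2 control and 2 construct 1 arrays. Higher expression of these genes by the cells carrying construct 1 remains a hypothesis, found and tested on the same data, and COL1A1, PDGFRB and FAP also stand on the mesenchymal list.

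The constructs shared 768 calls and differed in many more genes. A response in proportion to the fall of MECOM is argued against as the only cause. Of 2896 genes changed at least 2-fold with construct 2, 23.8% to 37.1% lay the other way on the construct 1 arrays. The spread of single arrays, pooled over groups that differ in it, would give 1.91%. A proportional response with a slide effect on the construct 2 arrays added is not excluded. The small spread of the construct 2 arrays, all on the same slide, leaves out differences between slides. Besides this spread, the median size of change over all genes was larger with construct 2, 0.414 (log2) against 0.258 with construct 1. A slide offset would enter the construct 2 changes, so these sizes cannot say what the larger count comes from. With slide as a block there were 2126 genes for construct 1 (slide as fixed terms) and 1462 for construct 2 (slide as a random block). These counts come from unlike models, so their order cannot be read. The fixed terms leave only the slide 1 arrays to compare construct 1 with control, while the spread also draws on the construct 2 arrays. Inside slide 1 alone 726 genes passed. Slide or scan cannot be told apart from construct 2, and with slide as a random block 2147 genes differed between the constructs. Hairpin effects on other genes and a response that needs a deeper fall of MECOM are candidate explanations that these data do not test.

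The remaining differences between the constructs are given as values. The median log2 difference of construct 2 from construct 1 was -0.387 for interferon response genes. It was 0.3162 for ribosome biogenesis and MYC target genes. It was 0.2481 for oxidative phosphorylation genes. It was -0.6417 for breast stem and progenitor genes. It was -0.4393 for reported EVI1 targets. MECOM itself differed by -0.6914. Among single genes, the log2 difference was 8.891 for LCN2, 7.394 for PDZK1IP1, 6.34 for CXCL1, 5.776 for C3 and 5.212 for ASB2. It was -4.636 for INHBB, -4.319 for ITGA10, -4.271 for TFF2, -4.243 for ANO2 and -4.218 for ATP10A.

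With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count of genes was as large in 1 of 10 splits for each construct and for the difference between them: 2009 for construct 1 (highest other split 1), 7473 for construct 2 (0) and 7847 between the constructs (1). For gene lists the real counts were 9, 5 and 7, reached by 3, 4 and 2 of 10 splits, and the highest other splits gave 10, 7 and 9 lists. For both constructs against control in a fit of 2 groups, 3 of 84 splits gave at least the real 319 genes. The splits that set the construct 2 arrays apart (7154 genes) and the construct 1 arrays apart (951) gave more, which points to a structure of the samples. Every split that mixed the groups gave at most 2 genes, since mixing them raises the spread. The share therefore shows that intact groups differ and cannot decide on chance for the 319 genes. The 7 lists called in that fit were reached by 26 of 84 splits (highest 12), so chance is not excluded. As many shared calls as the real 768 came from 4 of 100 drawn assignments, the real one included. The others that reached it had the construct 2 arrays in the place of the controls, with 4328 shared calls at most. Nearly all draws whose controls mixed the groups gave 0 shared calls, since mixing raises the spread. This share therefore cannot decide on chance.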

How the results depend on the processing

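The array weights fitted gene by gene, and the fit without the arrays alone on their slide, were chosen after the results were seen, and the other alternatives were planned. For each setting below that moved a result, the cause was not tested unless it is given. Limits come first: signal over background bounds what can be seen on arrays, one fit pools the spread of groups that differ in it, and slide cannot be separated from construct 2. Of 457 named gene calls, quantile normalization and the authors' values kept 457, the mean of a gene's probes 445, normexp 440, the replicate block 419, no filter 404, only the groups compared 402, array weights 364 and slide as a block 357. Of 27 list calls, camera with an estimated correlation kept 0 and fry 16. Over 26 settings, oxidative phosphorylation lost its call 7 times over both constructs and 6 times between them, and the ribosome list 7 times between them. PTPRC with construct 2 turned to -0.1735 with normexp (adjusted p = 0.566) and -0.5099 with the mean of its probes (adjusted p = 0.253), against adjusted p = 0.0413. Normexp moved the median of all genes between the constructs from 0.05 to 0.16 (log2), and 69.5% of the differing genes were then higher with construct 2 instead of 57.5%, while with quantile normalization, the percentile over bright probes and the authors' values the share was 50.7%, 49.8% and 50.7%. For construct 2 against control the share of rises was 58.1%, with 70.7% after normexp and 50.7%, 50.4% and 50.7% with those scalings. Over both constructs it was 54.95%, with 63.4% after normexp and 48.4%, 47.6% and 48.4%, so the balance of rises and falls depends on the scaling.

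With no filter on dim probes, where 36400 genes were tested, 943 genes changed with construct 1 and 2048 over both constructs, 306 were shared and 11 lists were called for construct 2. With only the groups compared in the fit, which has fewer arrays, 423 genes changed with construct 1 and 188 were shared. Array weights, whose estimation did not converge and which gave control replicate 2 a weight of 0.00507, left 587 genes for construct 1, 684 over both and 199 shared, but 12413 between the constructs. Weights fitted gene by gene gave 4895, 14257, 8942 and 12176 genes for construct 1, construct 2, both and the difference, and 2495 shared. With slide as a random block there were 1462 genes and 9 lists for construct 2, 1865 genes over both and 2147 between the constructs. MECOM then differed between the constructs by -0.7882 (limma adjusted p = 0.0647). Construct 1 against control was instead fitted with slide as fixed terms in this setting, which gave 2126 genes. The 239 shared calls and the r of 0.163 between the constructs with slide as a block therefore combine both models. Same-number arrays correlated at -0.202 to 0.162 after removing group means, which shows no pairing by replicate number. Slide enters these values too, so pairing is not excluded. With the number as a replicate block 1157 genes changed with construct 1 and 451 were shared. Camera with an estimated correlation called 0 lists in each of the 4 comparisons, and fry called 2, 12 and 11 for construct 1, construct 2 and the difference. For construct 1 fry kept only the protease (fry adjusted p = 0.00015) and fibroblast lists (0.00168) of those called by camera. For construct 2 it lost the mitosis list (0.121) and kept the others called by camera, the NF-kappaB list (0.000425) among them.

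Leaving out each array in turn gave 755 to 2879 genes for construct 1 (without control replicate 2 and 1), 4525 to 8741 for construct 2 (without construct 2 replicate 3 and construct 1 replicate 1), 1421 to 4439 over both (without control replicate 2 and 1) and 4967 to 9214 between the constructs (without construct 2 replicate 1 and control replicate 3). Shared calls ran from 252 to 1304 (without control replicate 2 and 1). MECOM differed between the constructs by -0.8186 to -0.5632. Without both arrays alone on their slide there were 2188, 10372, 4378 and 11598 genes for construct 1, construct 2, both and the difference.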

Other observations

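The tests named in this part were planned, except for KLRC3, which was chosen after its values were seen. KLRC1, KLRC3 and KLRC4 are neighbouring and closely related genes of natural killer cell receptors on chromosome 12, with probes between positions 10560240 and 10598822. KLRC3 was higher with construct 1 (adjusted p = 0.00324) and with construct 2 (adjusted p = 0.00169), and no size is given because it was above background on only 1 control array. Probes of such related genes can bind each other's transcripts, so these are not independent measurements. The pan-leukocyte marker PTPRC was at 0.63 with construct 2 (adjusted p = 0.0413), a call lost in 13 of 24 settings and reversed in sign in 2, and 2 of its 3 kept probes lay the opposite way, the lowest at -1.63.

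Several lists that were not called held members that changed. With construct 1, 3 of the p53 targets were higher and 3 lower, 7 and 4 adjusted over the list alone, with GDF15 at 2.56 ± 0.35, and the median of -0.04 differed in sign from the mean of 0.15 and from the test (upward, adjusted p = 0.784). With construct 2 these counts were 5 and 4, 7 and 4 adjusted over the list alone, and the median of -0.04 and the downward test (adjusted p = 0.901) differed in sign from the mean of 0.10. Anti-apoptotic genes had 2 higher and 0 lower with construct 1 (5 and 1 adjusted over the list alone, adjusted p = 0.813) and 6 and 6 with construct 2 (6 and 6 adjusted over the list alone, adjusted p = 0.89), where CFLAR, an inhibitor of caspase 8, was at 1.67 ± 0.16 and 1 of its 4 kept probes lay the opposite way (-0.34). TGF-beta targets had 4 and 2 with construct 1 (5 and 2 adjusted over the list alone, adjusted p = 0.813) and 4 and 9 with construct 2 (4 and 9 adjusted over the list alone, adjusted p = 0.377), where CCN2, an extracellular matrix signalling gene, was at -1.88 ± 0.26. Immediate early genes had 4 and 0 with construct 1 (5 and 2 adjusted over the list alone, adjusted p = 0.59) and 5 and 8 with construct 2 (6 and 8 adjusted over the list alone, median -0.21, adjusted p = 0.267), with FOS at -2.56 ± 0.24. The phosphatase gene DUSP5, which acts on ERK, rose with construct 1 (1.10 ± 0.12) and with construct 2 (1.39 ± 0.12).

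Among the signalling and adhesion lists, GPCRs had 4 higher and 8 lower with construct 1 (5 and 9 adjusted over the list alone, median -0.04, adjusted p = 0.602) and 9 and 17 with construct 2 (11 and 19 adjusted over the list alone, median -0.34, adjusted p = 0.114). G proteins and RGS genes had 4 and 3 with construct 1 (6 and 5 adjusted over the list alone, adjusted p = 0.813) and 9 and 7 with construct 2 (9 and 7 adjusted over the list alone, adjusted p = 0.89). Integrins and adhesion genes had 5 and 1 with construct 1 (11 and 4 adjusted over the list alone, median 0.11, adjusted p = 0.198) and 10 and 14 with construct 2 (10 and 15 adjusted over the list alone, median -0.33, adjusted p = 0.185), with ITGB3 at 1.27 ± 0.18 and -1.70 ± 0.18. Cholesterol synthesis genes had 3 and 1 with construct 1 (4 and 1 adjusted over the list alone, adjusted p = 0.784) and 6 and 3 with construct 2 (6 and 5 adjusted over the list alone, adjusted p = 0.951). Fatty acid synthesis genes had 1 and 2 with construct 1 (1 and 2 adjusted over the list alone, median -0.15, adjusted p = 0.0917) and 3 and 3 with construct 2 (3 and 3 adjusted over the list alone, adjusted p = 0.89).

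Luminal breast markers had 4 higher and 1 lower with construct 1 (5 and 3 adjusted over the list alone, median 0.05, adjusted p = 0.59) and 4 and 6 with construct 2 (4 and 6 adjusted over the list alone, median -0.22, adjusted p = 0.15). TFF3, a secreted trefoil peptide gene, was at 1.57 ± 0.12 with construct 1 and at -2.16 ± 0.12 with construct 2. Leukocyte markers had 2 and 1 with construct 1 (3 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.0974) and 3 and 1 with construct 2 (3 and 1 adjusted over the list alone, adjusted p = 0.89), where the median of -0.23 and the downward test differed in sign from the mean of 0.09. Endothelial markers had 2 and 1 with construct 1 (2 and 1 adjusted over the list alone, median 0.33, adjusted p = 0.447) and 0 and 3 with construct 2 (0 and 3 adjusted over the list alone, median -0.27, adjusted p = 0.267). For anti-apoptotic, TGF-beta, immediate early and cholesterol genes with construct 1 the median lay under 0 while mean and test were above it. With construct 2 median and mean were both above 0 for anti-apoptotic genes, G proteins and fatty acid genes while the test pointed down, TGF-beta targets had a median above 0 with mean and test below, and cholesterol genes a mean below 0 with median and test above.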
